A study of Rattus norvegicus with 6 samples.

How the data were processed

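Gene counts of 6 droplet libraries (10x Genomics) from rat cerebral hemisphere were analysed, 3 from the control group (NC) and 3 from the carbon monoxide group (CO), as the labels group them. The deposited files hold raw UMI counts per gene and barcode, not normalized. Reads were processed by the authors with Cell Ranger against the Rnor_6.0 genome, per the submitters' processing notes; the version is not given in the sources used here. The files used here hold 15227 genes and no mitochondrially encoded gene, so no mitochondrial filter was applied.

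Of 42293 barcodes, those with at least 500 UMIs and 200 genes were kept, which left out 10.4% of NC and 9.73% of CO barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. In CO replicates 01 and 02 it marked 8 and 1 barcodes, under 0.5%, so the highest 6% of scores, ties included, were removed there (391 and 369 barcodes). In all 679 NC and 913 CO barcodes were removed. Cells were merged without batch integration, and from the 2000 most variable genes, 30 principal components and 15 nearest neighbours, Leiden clustering (leidenalg 0.10.2, resolution 1) gave 54 clusters, of which 4 stayed unnamed. Clusters were named "X-like" from marker lists fixed before the data were examined, on at least 3 detected markers and the 10 leading genes. These naming details were chosen after seeing the data. Leading genes were taken against cells whose cluster had another best list, without which the CO endothelial-like cluster would stay unnamed. Hemoglobin genes alone did not name a cluster. Comparisons used the 11 classes with at least 30 cells in every library.

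The plan made before the data were examined treated the libraries as replicates. A check of the libraries compared each group's real split into libraries with random splits of its barcodes into parts of the same sizes (1000 splits, the real one included), over genes detected in at least 300 barcodes. Averaged over genes, the NC libraries differed by no more than such parts and the CO libraries by hardly more (one-sided permutation p = 0.358 and 0.028). The check used all barcodes, before filtering and removal of doublets, and did not cover shares of classes. Over 15 pairs of libraries, 1 barcode was shared. The number that separately prepared libraries would share was not worked out, so this does not show how the libraries were made. Each group was then counted as 1 sample, a departure from the plan made after seeing the data, although the CO value passes 0.05 and the series description speaks of 3 rats per group. The planned tests across libraries (edgeR, camera, fry, exact permutation, limma between classes) were not used for the comparisons. The edgeR fit is given in the closing section.

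Counts were summed per group and class and scaled to CPM, the usual unit for counts divided by the library total, with TMM factors (edgeR 4.0.16). A gene entered with at least 30 counts over both groups. Ratios are CO over NC. Their exact intervals come from the binomial distribution of the counts (scipy 1.17.1), shares carry exact Clopper-Pearson intervals, and a gene with a count of 0 was set to 3 counts over the group. The confidence level is 95% throughout, and intervals cover counting error only. Counts of genes at least 2-fold apart need a mean log2 CPM of at least 4. The median log2 ratio of each of the 28 gene lists was placed among 10000 random lists of the same size, drawn for each member from the 50 genes on each side in mean expression. Medians beyond the 2.5th or 97.5th percentile were taken to stand apart, as a description of these libraries, which held for 125 of 300 pairs of class and list. Lists of mitochondrially encoded genes, MHC class II genes and sex-linked genes, with 0, 2 and 4 members in the files used here, were not analysed here.

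Named genes were those with the highest and lowest ratios, 12 each way in microglia-like cells and in both phagocyte classes together and 4 each way elsewhere. They had the expression minimum above and no overlap between the values of the 3 CO and 3 NC libraries, which chance alone gives in 10% of genes. Of all genes compared, 24.8% in T- or NK-like cells, 56.4% in microglia-like cells and 70.7% over all kept cells had no such overlap. Passing this rule was therefore common and does not mark a gene out. Genes of the study's question were added in phagocyte classes whatever their values, as were the 4 members with the largest ratios of each list that stood apart. The adjusted p of the planned rule was dropped. Symbols that are only identifiers were not named, and some genes under this rule are not reported here.

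On simulated counts for microglia-like cells, intervals held the true ratio for 95.5% of 11536 unchanged genes, 96% of 100 genes changed 2-fold and 96% of 100 changed 4-fold. With the libraries as replicates, edgeR and DESeq2 1.42.0 each called all 100 and 100 of these genes, and 9 and 1 of 10655 unchanged ones. The simulated counts were drawn from 1 pooled profile, without variation between cells or animals, and their intervals used no TMM factors. They check the calculation only, not how far real libraries or rats differ. Alternatives covered RLE and total count scaling, doublets kept, cells thinned to 1000 UMIs without the 2273 NC and 1612 CO cells that held fewer, a minimum of 2000 UMIs, resolution 0.5, naming by marker score, another denominator for shares and each library left out. List medians were placed among 2000 random lists in each alternative. Total count scaling and the minimum of 2000 UMIs were added after the data were seen.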

Results

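Single-cell transcriptomes of the rat cerebral hemisphere were compared between control rats (NC) and rats with acute carbon monoxide poisoning (CO). Per the series description, CO rats inhaled 1000 ppm of the gas for 40 minutes and then 3000 ppm for 20 minutes. Severe poisoning was taken as impaired consciousness with more than 60% carboxyhemoglobin, the form of hemoglobin that has bound CO. There were 3 libraries per group. The unique molecular identifiers (UMIs, 1 per captured transcript) numbered 45149091, 42448680 and 47322264 in the NC libraries and 42975621, 39494470 and 42907958 in the CO libraries. After filtering, 19579 NC cells with a median of 4740 UMIs and 16856 CO cells with a median of 5548 UMIs remained.

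Averaged over genes, the libraries of a group differed by no more (NC), or hardly more (CO), than random splits of 1 pool of cells. The spread between library means, relative to the variance of single cells and averaged over 10859 genes, was 2.02 among the NC libraries, against a median of 1.99 and a 95% range of 1.85 to 2.25 over random splits of the barcodes (one-sided permutation p = 0.358). Among the CO libraries it was 2.24 over 10806 genes, against 1.98 and 1.85 to 2.25 (one-sided permutation p = 0.028). A simulated difference between libraries with an SD of 0.05 in log level gave 4.73 in NC and 4.80 in CO. The series description speaks of 3 rats per group, but the spread between these libraries was about that of cells drawn from 1 pool and gives no measure of differences between rats. The libraries of each group were therefore counted as 1 sample (n = 1 per group). Differences between the groups are therefore given without p-values. The closing observations give the calls of a fit that took the libraries as replicates, and library values entered the choice of named genes, but neither is a check on separate rats. Signed values given for genes are log2 ratios, CO over NC, with their interval, and highest levels are among the classes compared. All intervals are 95% and cover counting error only.

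Microglia-like cells made up more of the CO cells and oligodendrocyte-like cells less. Microglia, the resident phagocytes of the brain, were 36.9% (36.2% to 37.6%) of NC cells and 49.3% (48.5% to 50.1%) of CO cells (exact binomial intervals). Oligodendrocyte-like cells, which form myelin, were 16.9% (16.3% to 17.4%) and 8.19% (7.78% to 8.62%), and macrophage-like cells 3.12% (2.88% to 3.37%) and 2.40% (2.18% to 2.65%). Neuroblast-like cells, the young neurons of the ventricle wall, were 2.10% (1.90% to 2.31%) and 6.89% (6.51% to 7.28%). Neutrophil-like cells were 0.225% (0.163% to 0.302%) and 0.736% (0.612% to 0.876%), a ratio of 3.27 that was 1.88 with doublets kept, 1.998 by marker score and 11.4 over cells of at least 2000 UMIs, and 49 of the CO cells lay in a cluster with no NC cell and a median of 790 UMIs. That cluster had 2 neutrophil markers among its 10 leading genes and 2 of other classes, with the neuronal genes *Tubb3* and *Stmn2* among these 10, and its counterpart stayed unnamed with doublets kept. Endothelial-like cells were 14.5% and 11.8%, astrocyte-like cells 3.07% and 4.63%. Unnamed clusters held 10.5% of NC and 2.02% of CO cells, among them 1633 NC and 95 CO cells of a cluster led by the hemoglobin gene *Hba-a1*, with a median of 882 UMIs. Choroid plexus-like cells were 1.91% and 3.99%, but 490 of the CO cells lay in a cluster with a median of 1272 UMIs. Their ratio, CO over NC, turned to 0.964 when cells under 2000 UMIs were left out and to 0.794 when cells were named by marker score. By that score ependymal-like (1.38 against 0.918), B-like (0.446 against 1.77), erythroid-like (4.07 against 0.648) and neuron-like ratios (0.335 against 1.81) turned as well. Naming by score left no cell unnamed, so the cells of unnamed clusters entered these classes. Erythroid-like cells of NC then held 1738314 UMIs in place of 14056. The erythroid-like ratio of 4.07 rested on only 4 NC and 14 CO cells. It was 2.65 without NC replicate 03, 2.62 without CO replicate 01 and 7.69 from 2000 UMIs. The neuron-like class held a cluster of 215 NC and 2 CO cells led by *Cga* and *Tshb*, which encode subunits of pituitary hormones. Its other cluster, led by the neuronal genes *Snap25* and *Slc17a7*, held 7 NC and 62 CO cells with a median of 813 UMIs. The lower ratio of the class therefore came from the first cluster, and the second went the other way. Shares of a dissociated tissue also depend on what was dissected, which was not compared between the groups here, and on which cells survived digestion. Libraries of 1 group differed in some shares. Choroid plexus-like cells ranged from 3.40% to 5.07% over the CO libraries and B-like cells from 0.293% to 0.699% over the NC libraries. The check of the libraries averaged over genes and did not cover shares, and the binomial intervals of the pooled cells leave such spread out.

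**Figure D1:**
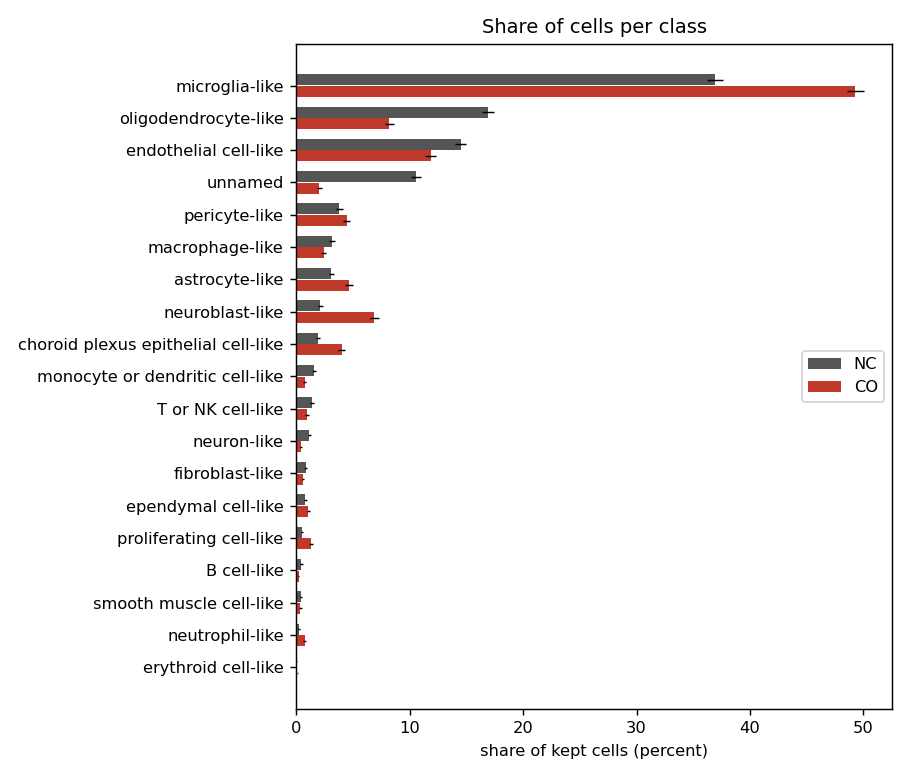
Share of kept cells in each class (horizontal axis, percent) for the pooled NC and CO cells; error bars are exact 95% binomial intervals, which cover counting error only. Microglia-like cells were 36.9% of NC and 49.3% of CO cells.

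The series title names the cytokine CLCF1, NF-κB signalling and macrophage efferocytosis, the uptake of dying cells. *Clcf1* itself was close to absent from phagocytes, with 9 UMIs among 7229 NC and 6 among 8309 CO microglia-like cells (log2 ratio -0.89, interval -2.67 to 0.76). Macrophage-like cells held 5 and 3 (-0.38, interval -3.07 to 1.98), so no difference was detectable at this depth. *Il6st*, the shared signalling receptor of this cytokine family, was at 148 CPM (counts scaled to the same total) in NC and 167 CPM in CO microglia-like cells (log2 ratio 0.18, 0.13 to 0.23). The kinase gene *Jak1* was at 0.34 (0.31 to 0.38) and the receptor gene *Il6r* at 0.29 (0.25 to 0.33), while *Lifr*, highest in endothelial-like cells, was at 0.892 and 4.58 CPM (log2 ratio 2.36, 1.53 with thinned cells). Of the measured members of the CLCF1 receptor list, 9 of 10 were higher in CO microglia-like cells (median 0.21, percentile 97.7 of random lists matched on expression). The median lay within the random range without NC replicate 02 (0.19), NC replicate 03 (0.19), CO replicate 01 (0.20) or CO replicate 03 (0.17), with doublets kept (0.23) and by marker score (0.18). In macrophage-like cells 4 of 9 were higher (median -0.079, percentile 26.2).

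NF-κB target genes were lower in CO in both phagocyte classes. In macrophage-like cells 23 of 26 measured targets were lower (median -0.56, below all 10000 random lists). *Nfkbia*, the inhibitor that NF-κB itself induces, was at 3528 and 1644 CPM in NC and CO there (-1.10, interval -1.16 to -1.04), and the survival gene *Bcl2a1* at 1414 and 651 CPM (-1.12, interval -1.21 to -1.03). *Birc3* was at -1.32 (-1.63 to -1.01), but at 0.35 with clustering at resolution 0.5. In microglia-like cells 19 of 27 targets were lower (median -0.23, below all 10000 random lists), with *Gadd45b* at -0.87 (-0.93 to -0.80), *Nfkbid* at -0.70 (-0.78 to -0.62) and *Nfkbia* at -0.27 (-0.28 to -0.25). Single targets there went the other way, such as *Il1b*, an inflammatory cytokine gene, at 0.39 (0.36 to 0.42) and the prostaglandin synthase gene *Ptgs2* at 0.74 (0.60 to 0.87); in macrophage-like cells *Il1b* was at -0.39 (-0.43 to -0.34). The factor gene *Nfkb1* was at 0.38 (0.35 to 0.42) in microglia-like and -0.76 (-0.90 to -0.62) in macrophage-like cells, the latter at -0.095 at resolution 0.5. *Rela* was at 0.072 (-0.017 to 0.16) and -0.72 (-1.10 to -0.36), the latter at 0.051 with cells thinned to equal depth. The pathway components as a list stood at median 0.072, percentile 86.5 in microglia-like cells and median -0.28, percentile 2.27 in macrophage-like cells. That second value lay within the random range without NC replicate 02 (-0.25), NC replicate 03 (-0.23) or CO replicate 02 (-0.18), with thinned cells (-0.088), by marker score (-0.24) and from 2000 UMIs (-0.22).

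Receptors and bridging factors of efferocytosis had no common direction, and the sign of their median, close to 0 in both phagocyte classes, changed with the processing. It fell below 0 in microglia-like cells when scaled by total counts or without CO replicate 02, and lay above 0 in macrophage-like cells when thinned, at resolution 0.5, by marker score or without NC replicate 03. In microglia-like cells 15 of 28 were higher and in macrophage-like cells 11 of 25 (median 0.041, percentile 51.6, and median -0.088, percentile 12.4). *Mertk*, a receptor for dying cells, was at 1137 and 820.0 CPM in NC and CO microglia-like cells (-0.47, interval -0.49 to -0.45). In macrophage-like cells it was at -0.15 (-0.29 to -0.015), at 0.025 without CO replicate 03 and at 0.027 by marker score. *Axl*, a related receptor, was at 8.52 and 14.7 CPM in microglia-like cells (0.79, interval 0.59 to 0.99) and at -0.088 (-0.39 to 0.21) in macrophage-like cells, there at -0.71 at resolution 0.5 and above 0 with doublets kept. *Trem2*, a lipid-sensing receptor, was at 0.098 (0.082 to 0.11) and 0.57 (0.45 to 0.70). The ligand genes *Gas6* and *Mfge8* were at 0.022 (-0.043 to 0.087) and 0.23 (0.16 to 0.30) in microglia-like cells, the former below 0 when scaled by total counts, thinned or without CO replicate 01, and *Mfge8* was highest in astrocyte-like cells (823 CPM in NC). Genes of engulfment and corpse processing were higher in CO microglia-like cells in 26 of 35 cases (median 0.16, percentile 99.62), although *Dock1* was at -1.35 (-1.52 to -1.19); in macrophage-like cells 17 of 33 were higher (median 0.011, percentile 46). *Hmox1*, which degrades heme and releases CO, was lower in both classes, at -0.69 (-0.71 to -0.68) in microglia-like and -0.49 (-0.56 to -0.43) in macrophage-like cells.

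Among single genes of microglia-like cells, 41 of 6242 compared were at least 2-fold higher in CO and 31 at least 2-fold lower. Among genes past the expression minimum, the highest ratios belonged to *Fcrla* (13.2 and 68.2 CPM, 5.16-fold), *Mycl* (4.98-fold), *Plac8* (3.82-fold) and *Fkbp5*, a gene induced by glucocorticoids (60.3 and 227 CPM, 3.77-fold). *Rab30*, *Zfat*, *Tie1*, *Pstpip1*, *Cd4*, *Smim3*, *Hist2h2ac* and *Trpv3* followed, at 3.52-fold to 2.78-fold. By marker score the log2 ratio of *Fcrla* was 1.67 in place of 2.37. *Fcrla*, *Mycl*, *Plac8* and *Pstpip1* were higher in monocyte- or dendritic-like than in microglia-like cells of NC. The lowest ratios belonged to *Sdc4*, a cell surface proteoglycan gene (45.4 and 6.33 CPM, 7.18-fold lower), *Grxcr1* (3.46-fold), *Klf12* (3.42-fold), *Fam111a* (3.20-fold), *Cav1* (3.11-fold), the potassium channel gene *Kcna2* (3.10-fold), the collagen chaperone gene *Serpinh1* (2.60-fold) and *Fchsd2* (1327 and 525 CPM, 2.53-fold). *Sdc4* was highest in macrophage-like cells (1148 CPM in NC). *Ppp1r14a*, *Ptgds*, *Apod* and *Cryab* were also among the 12 lowest, at 2.70-fold to 2.32-fold, and each was highest in oligodendrocyte-like cells, where *Ptgds* reached 8459.6 CPM in NC against 85.8 CPM in microglia-like cells.

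**Figure D2:**
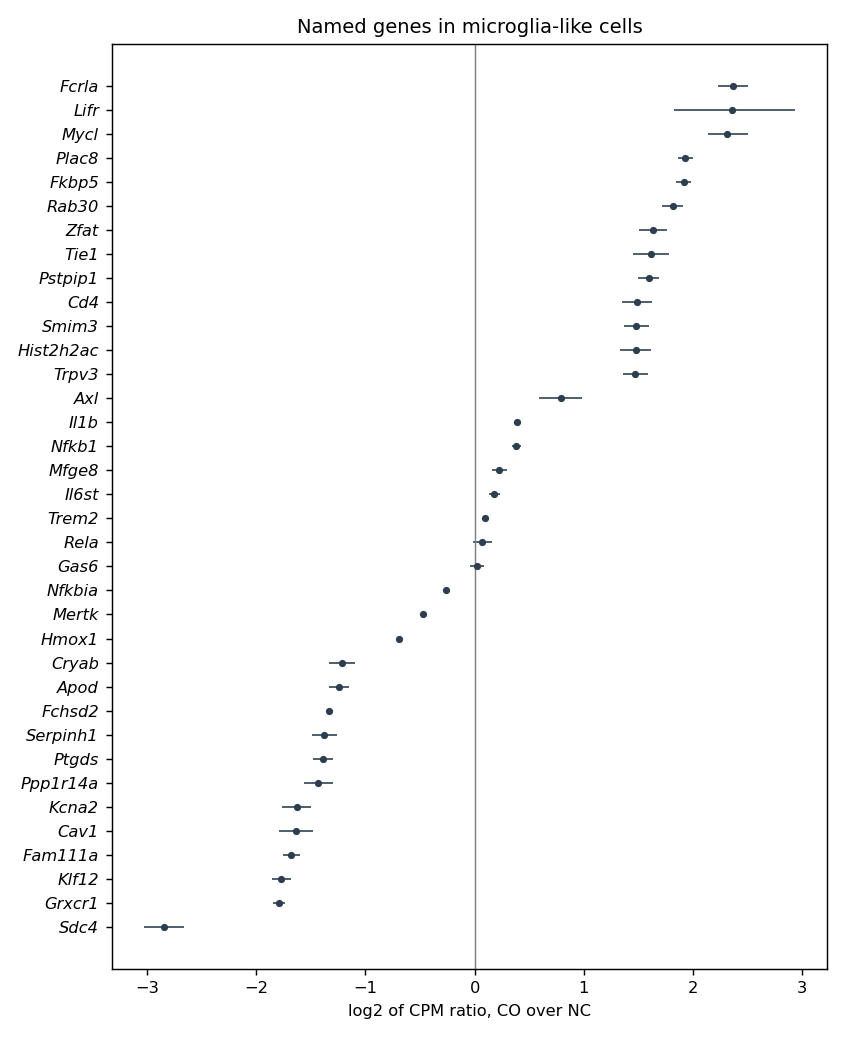
Log2 ratio of CPM, CO over NC (horizontal axis), for the genes named by size or by the study's question in microglia-like cells, with at least 30 UMIs; points are the pooled groups and bars 95% counting intervals. The points run from -2.84 for *Sdc4* to 2.37 for *Fcrla*.

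Stress and activation genes of microglia-like cells stood apart in opposite directions. All 14 measured heat shock genes were lower in CO (median -0.31, below all 10000 random lists), with *Hspa1b* at 4289.6 and 3036 CPM (-0.50, interval -0.51 to -0.49). Of the genes of the unfolded protein and integrated stress response 16 of 21 were lower (median -0.35, below all 10000 random lists), among them the chaperone gene *Hspa5* at 1377 and 625 CPM (-1.14, interval -1.16 to -1.12) and *Manf* at -1.03 (-1.07 to -0.99). Immediate early and dissociation response genes were lower in 20 of 26 cases (median -0.15, percentile 0.07), including the nuclear receptor genes *Nr4a1* at -0.69 (-0.72 to -0.67) and *Nr4a2* at -0.91 (-0.96 to -0.86). Disease-associated microglia genes were higher in 16 of 23 cases (median 0.28, percentile 99.96), with *Gpnmb* at 1.40 (1.13 to 1.69) and *Lgals3* at 1.22 (0.97 to 1.47), the latter at 2.31 with thinned cells, while *Lpl* was at -1.89 (-2.92 to -0.96). On the reactive astrocyte list, 12 of 18 genes were higher (median 0.46, above all 10000 random lists); its members with the largest ratios in microglia-like cells were *Fkbp5*, the complement gene *C3* (114 and 312 CPM, 1.46, interval 1.41 to 1.51), the lipopolysaccharide co-receptor gene *Cd14* (1.40, interval 1.24 to 1.55) and the astrocyte filament gene *Gfap* (1.21, interval 0.82 to 1.62), whose own class had the higher share in CO. By marker score the median of this list lay within the random range (0.091). Targets of hypoxia-inducible factor were lower in 16 of 25 cases (median -0.15, percentile 1.28), within the random range without NC replicate 02 (-0.11), with thinned cells (-0.10) or from 2000 UMIs (-0.15). Myelin genes were lower in 15 of 19 cases (median -1.04, below all 10000 random lists), and oligodendrocyte-like cells, which carry these transcripts, also had the lower share in CO. Hemoglobin genes were lower in 5 of 5 cases (median -0.56, percentile 0.19), within the random range by marker score (-0.33). Over all barcodes, hemoglobin genes held a higher share of the UMIs in each CO library (0.258% to 0.329%) than in each NC library (0.187% to 0.243%), as did genes of ribosomal proteins (6.81% to 6.89% against 5.60% to 5.64%). The lists of neutrophil and neuronal genes had medians above 0 in microglia-like cells. Of the neutrophil genes 4 of 6 were higher (median 1.01, percentile 99.0), with *S100a9* at 8 and 64 UMIs (2.69, interval 1.63 to 3.96) but *Ngp* at -2.31 (-3.47 to -1.28), and neutrophil-like cells also had the higher share in CO. Their median lay within the random range from 2000 UMIs (0.98) and without NC replicate 01 (0.66), NC replicate 03 (0.70), CO replicate 01 (0.62) or CO replicate 03 (0.78). *S100a8* was at 3.12 (1.81 to 4.80), at 2.32 from 2000 UMIs and at 3.82 (1.89 to 6.90) without NC replicate 03. Of the neuronal genes 6 of 9 were higher (median 0.63, percentile 99.67), with *Stmn2* at 52 and 238 UMIs (1.88, interval 1.45 to 2.35) and highest in neuroblast-like cells, whose share was also higher in CO. That median lay within the random range with thinned cells (0.20) or without CO replicate 02 (0.13).

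**Figure D3:**
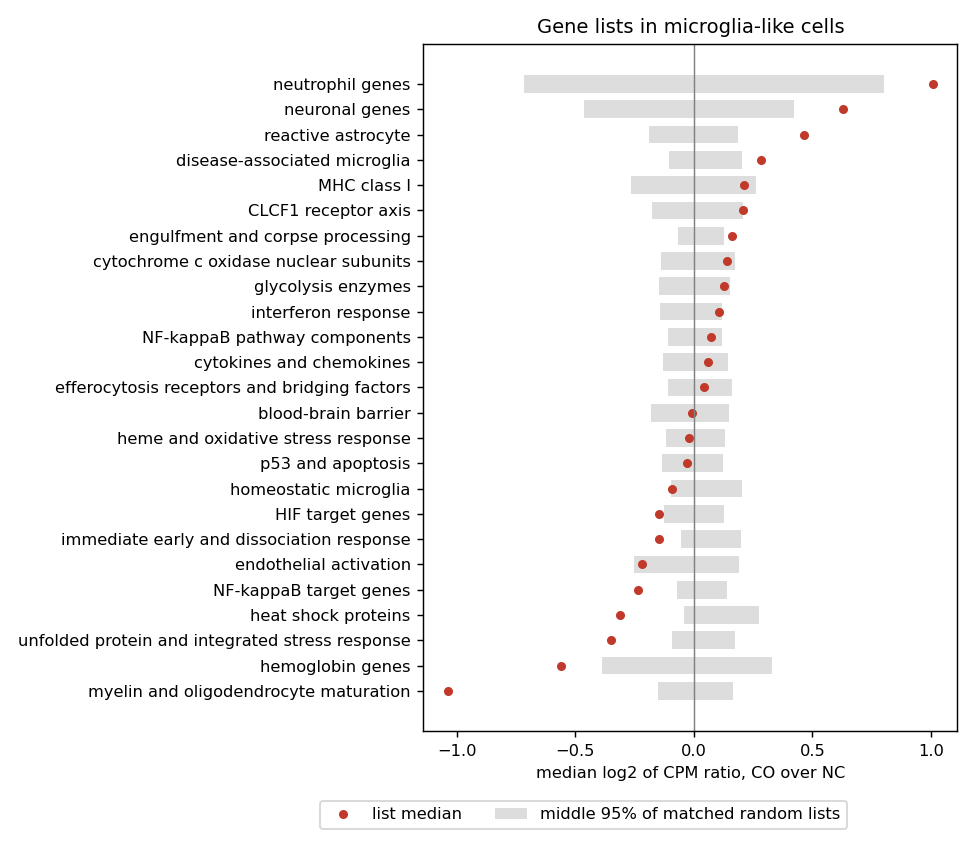
Median log2 ratio, CO over NC (horizontal axis), of each gene list in microglia-like cells (points) and the middle 95% of 10000 random lists of the same size matched on expression (grey bars). The myelin list lies at -1.04 and the heat shock list at -0.31, both below their grey bars.

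In macrophage-like cells 190 of 6159 genes were at least 2-fold higher in CO and 233 at least 2-fold lower, over 610 NC and 405 CO cells, so counting noise adds to these numbers. *Il1r2*, the decoy receptor of interleukin 1, was at 4.10 and 84.4 CPM (20.6-fold higher), *Mgst2*, a glutathione transferase gene, at 7.84 and 107 CPM (13.7-fold), and *Trpv3* and *Xxylt1* were 5.38-fold and 5.36-fold higher. The log2 ratio of *Il1r2* was 4.36, against 3.56 without CO replicate 01, 2.91 with doublets kept, 4.99 from 2000 UMIs, 2.18 by marker score and 0.92 at resolution 0.5. The basement membrane collagen genes *Col4a3* and *Col4a4* were 9.27-fold and 6.22-fold lower, and both were highest in pericyte-like cells. The protease gene *Adamts1* was 7.47-fold lower, and *Clec4e*, a receptor for microbial and dead-cell ligands, 7.37-fold lower. The log2 ratios of *Mgst2* (3.77), *Col4a3* (-3.21), *Col4a4* (-2.64), *Adamts1* (-2.90) and *Clec4e* (-2.88) also moved by over 1.5 times. At resolution 0.5 *Mgst2* at 2.38 and *Col4a4* at -1.70 stood closer to 0, as did *Col4a3* at -1.50 and *Col4a4* at -1.87 by marker score. With thinned cells *Adamts1* at -1.70 stood closer and *Mgst2* at 4.54 (2.90 to 6.87) and *Clec4e* at -3.86 (-6.95 to -1.92) further, the last 2 over no more than 3 UMIs in 1 group. From 2000 UMIs *Adamts1* was at -3.60. Interferon response genes were lower in 19 of 26 cases (median -0.38, percentile 0.09; within the random range with thinned cells, -0.27), with *Gbp2* at -2.47 (-3.48 to -1.59). Genes of the unfolded protein response were lower in 17 of 18 (median -0.45, percentile 0.10), with *Hsp90b1* at -0.88 (-1.02 to -0.73), and heat shock genes in 13 of 14 (median -0.27, percentile 0.47). Myelin genes were lower here too (median -0.84, below all 10000 random lists), as were homeostatic microglia genes (median -0.59, below all 10000 random lists), the latter at -0.072 without NC replicate 02, -0.26 with doublets kept and 0.032 by marker score.

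With both phagocyte classes summed, 33 of 6293 genes were at least 2-fold higher and 36 at least 2-fold lower. Macrophage-like cells were 610 of the 7839 NC and 405 of the 8714 CO cells summed, so the mix of the 2 classes also enters these values. *Fcrla* (5.36-fold), *Mycl* (4.83-fold) and *Plac8* (3.91-fold) again had the highest ratios, and *C3* (2.81-fold) and *Siglec5* (2.78-fold) joined the 12 highest. By marker score the log2 ratio of *Fcrla* was 1.73 in place of 2.42. *Sdc4* (4.04-fold) and *Grxcr1* (3.36-fold) were lowest, and the neutrophil-attracting chemokine gene *Cxcl1* was at 684 and 263 CPM (2.60-fold lower). *Cxcl1* was among the leading genes of the macrophage-like cluster. *Il1b* was at 0.058 (0.036 to 0.081), and at -0.015 when scaled by total counts and -0.090 with thinned cells. Targets of NF-κB were lower in 20 of 27 cases (median -0.24, below all 10000 random lists).

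Endothelial-like cells, which line the vessels, lay in different clusters in the groups, with 1846 NC and 46 CO cells in 1 cluster and 41 NC and 1814 CO cells in another. Over the whole class, 210 of 6775 genes were at least 2-fold higher and 134 at least 2-fold lower. The hormone gene *Stc1* was 11.4-fold higher in CO, *Mt2A*, which encodes a metal-binding metallothionein, 9.97-fold (68.0 and 679 CPM), *Tnfrsf12a*, the TWEAK receptor gene, 9.40-fold and the tubulin gene *Tuba1c* 8.69-fold. *Tspan8*, *Rgs1*, *Fam111a* and the MHC class II invariant chain gene *Cd74* were 12.6-fold, 5.31-fold, 4.82-fold and 4.77-fold lower, each with its highest level in a myeloid class. The log2 ratio of *Rgs1* was -2.41, -3.20 without CO replicate 03 and -0.54 with doublets kept and -1.65 thinned. That of *Cd74* was -2.25, -0.89 with doublets kept, -1.03 thinned and -0.72 by marker score, and that of *Tspan8* -3.66, -2.30 with doublets kept and -4.48 thinned. Glycolysis enzymes were higher in 12 of 16 cases (median 0.55, percentile 99.99), with the lactate dehydrogenase gene *Ldha* at 183 and 557 CPM (1.61, interval 1.55 to 1.67) and *Pfkp* at 1.57 (1.41 to 1.73). Reactive astrocyte list genes were higher in 13 of 19 cases (median 0.31, percentile 99.3), with *Lcn2*, an iron-carrier binding protein gene, at 39.4 and 178 CPM (2.17, interval 2.05 to 2.30). NF-κB targets were lower in 19 of 27 (median -0.59, percentile 0.01), within the random range with doublets kept (-0.10). Genes of other classes were lower beside them, with medians of -1.06 for homeostatic microglia, -1.80 for hemoglobin and -1.24 for myelin genes. The first of these was -0.033 with doublets kept and -0.42 with thinned cells, and the second 0.18 by marker score. By that score *Hba-a1* (-1.91) turned to 0.052 (-1.21 with doublets kept) and *Bcl2a1*, an NF-κB target, to 0.024. Scaling by total counts shifted all log2 ratios of this class by -0.13 and those of monocyte- or dendritic-like cells by -0.10.

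In oligodendrocyte-like cells 47 of 6590 genes were at least 2-fold higher and 20 at least 2-fold lower (87 and 48 with thinned cells, and 34 lower with doublets kept). *Cd59*, an inhibitor of complement, was 6.52-fold higher, *Scube2* 5.43-fold, *Spata22* 4.71-fold and the channel gene *Trpv3* 4.32-fold, while the ligand gene *Eda* was 14.9-fold, *Rhbdl2* 8.52-fold, *Fam135b* 4.24-fold and *Cobll1* 4.07-fold lower. With doublets kept the log2 ratio of *Eda* was -3.09 in place of -3.89. Their own myelin genes had no common direction (9 of 19 higher; median -0.046, percentile 49.3). Immediate early genes were lower in 20 of 25 cases (median -0.50, below all 10000 random lists) and cytokines in 13 of 17 (median -0.70, below all 10000 random lists).

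In astrocyte-like cells 202 of 8182 genes were at least 2-fold higher and 222 at least 2-fold lower (312 and 339 with thinned cells). The largest cluster of this class was another in each group, with 233 NC and 217 CO cells in 1 and 144 and 348 in one with a median of 769 UMIs. *Lyz2*, *Fkbp5* and *Car3* were 11.6-fold, 9.57-fold and 9.03-fold higher. *Lyz2* was highest in monocyte- or dendritic-like cells of NC, and the list of homeostatic microglia genes was also higher in CO here (median 0.76, percentile 99.96). With doublets kept that median was 0.066, within the random range. Without CO replicate 01 the log2 ratio of *Lyz2* was 1.78 in place of 3.54, and by marker score 2.33, while *Car3* (3.18) was then at 3.87. *Pomc*, a hormone precursor gene of pituitary and hypothalamus, was at 947 and 13.3 CPM (-6.16, -5.34 without NC replicate 01, -2.55 with doublets kept, -3.73 thinned and 0.0093 by marker score). *Ifi27l2b*, *Dcc*, an axon guidance receptor gene, and *Tango6* were 13.9-fold, 13.7-fold and 7.55-fold lower, and *Dcc* stood at -3.77, against -4.40 without CO replicate 03 and -4.45 by marker score. *Ifi27l2b* stood at -3.80, against -2.48 with doublets kept, -1.92 thinned and -1.14 by marker score.

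*Tnfrsf12a* was among the highest in 3 further classes. It was 22.6-fold higher in choroid plexus-like, 13.6-fold in ependymal-like (log2 ratio 3.77, 4.56 (2.99 to 6.85) without NC replicate 01) and 13.3-fold in pericyte-like cells. *Scx*, a transcription factor gene of connective tissue, was 8.91-fold higher in choroid plexus-like cells, and the interferon-induced gene *Isg15* 5.63-fold lower. *Calcrl* and *Cd83* were also 24.2-fold and 9.64-fold higher there, with their highest NC levels in microglia-like and macrophage-like cells, and homeostatic microglia genes stood at 1.60. Choroid plexus-like cells lay mostly in different clusters in the groups, with 326 NC and 182 CO cells in 1 and 47 NC and 490 CO cells in another, with medians of 47084 and 1272 UMIs. The log2 ratio of *Calcrl* (4.59) was 2.93 by marker score, 3.27 from 2000 UMIs and 7.999 (5.51 to 13.31) thinned, and that of *Cd83* (3.27) 0.96, 2.57 and 6.97 (4.47 to 12.28), with 1 NC UMI of each left after thinning. With thinned cells *Tnfrsf12a* was at 3.22 there in place of 4.50, and at 3.08 in pericyte-like cells in place of 3.73. In ependymal-like cells *Tiam2* was 28.0-fold higher (4.81, 5.48 (3.92 to 7.76) without NC replicate 02), the tight junction gene *Cldn5* 19.6-fold and *Pmepa1* 17.7-fold higher. By marker score the log2 ratio of *Cldn5* was 0.69 in place of 4.29, that of *Pmepa1* 2.44 in place of 4.14 and that of *Tiam2* 4.10. With thinned cells *Pmepa1*, then with 1 NC UMI, was at 4.82 (2.24 to 10.17). In pericyte-like cells, which wrap capillaries, *Mt2A* was 26.4-fold higher (4.72, 4.10 without CO replicate 03), *Tmem252* 10.3-fold and *Dapk1*, a death-associated kinase gene, 9.99-fold. *Cxcl1* was 6.52-fold lower there (-2.70, -1.54 without NC replicate 01, -4.07 with doublets kept and -3.44 thinned). The genes at least 2-fold higher and lower numbered 192 and 106 of 5986 in choroid plexus-like, 274 and 338 of 7509 in ependymal-like and 216 and 145 of 7576 in pericyte-like cells. With thinned cells they numbered 654 and 415 in choroid plexus-like and 95 and 112 in ependymal-like cells, and 301 were lower in pericyte-like cells.

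In neuroblast-like cells the potassium channel gene *Kcnj3* was 7.29-fold and the adhesion gene *Cntn4* 4.23-fold higher in CO, and *Mgp*, a calcification inhibitor gene that was highest in pericyte-like cells, 5.18-fold lower. The largest cluster of this class differed between the groups, with 233 NC and 495 CO cells in 1 and 132 and 573 in another. With thinned cells the log2 ratio of *Kcnj3* was 1.95 in place of 2.87 and that of *Mgp* -1.60 in place of -2.37. *Kcnk13*, highest in microglia-like cells, was at -3.31, and at 2.09 with doublets kept. T- or NK-like cells held 229 NC and 110 CO cells in a cluster with the T cell genes *Cd3g* and *Cd3d* among its leading genes, and 42 and 46 in one led by *Ccl5*, *Xcl1* and *Gzma*, genes of cytotoxic cells. Over the class the natural killer receptor gene *Klrc3* was 22.5-fold higher (log2 ratio 4.49, 5.12 without NC replicate 02) and the histone gene *Hist1h2ah* 8.07-fold. The 4 genes named for the lowest ratios there were each highest in endothelial-like or pericyte-like cells. The chemokine gene *Cxcl12*, highest in endothelial-like cells, was 50.3-fold lower (-5.65, -5.05 without CO replicate 01, -2.75 with doublets kept and -2.58 by marker score). *Igfbp7*, a vascular gene highest in pericyte-like cells, was 20.0-fold lower (-4.32, -2.43 with doublets kept and -1.77 by marker score). *Cldn5* and *Csrp2*, highest in endothelial-like cells, were at -4.52 (-5.67 to -3.58) and -4.29 (-5.08 to -3.59). For *Cldn5* the value was -0.71 by marker score, -3.75 with doublets kept, -5.70 from 2000 UMIs, -3.71 without NC replicate 03 and -3.92 without CO replicate 03, and for *Csrp2* -3.63 by marker score and -3.01 without NC replicate 03. Blood-brain barrier genes were lower in 11 of 15 cases (median -0.92, percentile 0.05), within the random range with thinned cells (-0.17). The mix of clusters in monocyte- or dendritic-like cells differed between the groups. There were 215 NC and 58 CO cells in 1, led by *G0s2* and *Fcnb*, and 86 NC and 66 CO cells in another, led by *Slpi* and *Cd74*. Values of the whole class were not split by cluster. *Mt2A* was 20.3-fold higher (log2 ratio 4.34, 3.64 without NC replicate 01, 3.72 without CO replicate 02, 3.39 at resolution 0.5 and 2.57 by marker score). *Fcgr3a*, an antibody receptor gene, was 6.24-fold lower (-2.64, -0.37 by marker score). *Cxcl1* was at 895 and 13.4 CPM there (-6.06, -7.36 without CO replicate 03, -2.94 with doublets kept and -0.46 by marker score). It was at most -4.77 thinned and at most -6.84 at resolution 0.5, where CO held 0 UMIs and was set to the floor of 3 UMIs over the group. Genes at least 2-fold higher and lower numbered 127 and 85 of 7099 in neuroblast-like, 442 and 404 of 6219 in T- or NK-like and 397 and 381 of 6045 in monocyte- or dendritic-like cells. T- or NK-like cells numbered 271 in NC and 156 in CO, monocyte- or dendritic-like cells 301 and 124. Counting noise adds to such numbers of genes, so they do not rank the classes. With thinned cells they were 301 and 171 in neuroblast-like and 142 and 168 in T- or NK-like cells. Monocyte- or dendritic-like cells then had 209 higher, and 745 higher and 674 lower at resolution 0.5.

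Over all kept cells, where composition and expression mix, 91 of 7908 genes were at least 2-fold higher and 153 at least 2-fold lower. *S100a9*, a calcium-binding protein gene of neutrophils, was at 4.21 and 174 CPM in NC and CO (log2 ratio 5.37, 6.37 without NC replicate 01), *Mt2A* at 41.0 and 224 CPM, *Tnfrsf12a* at 14.1 and 73.6 CPM (2.39, 1.75 thinned) and *Tmem252* at 15.4 and 73.8 CPM. Of the neutrophil genes 10 of 11 were higher (median 2.25, above all 10000 random lists), and of the reactive astrocyte genes 17 of 22 (median 0.45, above all 10000 random lists), the latter within the random range with thinned cells (0.086). *Cga* was 6.98-fold lower (-2.80, -3.43 without CO replicate 02 and -3.83 thinned), and *Eda*, *Jhy* and the potassium channel gene *Kcnq3* were 4.49-fold, 4.02-fold and 3.69-fold lower, these 3 highest in oligodendrocyte-like cells. Myelin genes were lower in 18 of 19 cases (median -1.11, below all 10000 random lists).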

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

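The tests of *Mt2A* reported here were chosen after its values were seen, except that of depth in microglia-like cells, whose outcome was set down beforehand.

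Barcodes under the cell filter, which no comparison used, held *Mt2A* at 467 CPM in CO (417 to 521), above 98.3 CPM in NC. RNA free in the suspension could carry such transcripts into all droplets. As for the level alone, *Mt2A* in CO lay above that of these barcodes in 3 classes, with no overlap of intervals. These were endothelial-like (71.2 CPM in NC and 649 CPM in CO before TMM scaling), astrocyte-like (301 and 1249) and ependymal-like cells (869 and 2865). They were picked with their values known, and no other class lay above that level. Free RNA alone would not give such levels in CO. In astrocyte-like and ependymal-like cells, however, the NC level too lay above the 98.3 CPM of NC barcodes. There the level in CO does not bear on the rise, while the NC level of endothelial-like cells lay below 98.3 CPM. The part of free RNA in the ratios of these 3 classes was not tested. Depth is argued against by log2 ratios of 3.36 (3.11 to 3.61) in endothelial-like and 2.38 (1.52 to 3.36) in microglia-like cells after thinning to equal depth. Free RNA and expression cannot be told apart in the 7 other classes with *Mt2A* in both groups, since 2 of them, pericyte-like (4.66) and monocyte- or dendritic-like cells (4.24), had a log2 ratio above that of the barcodes (2.25), while microglia-like cells were at 2.25, and the share of free RNA per droplet was not measured. Poisoning, handling and differences between animals stay open, untested.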

How the results depend on the processing

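All values here are alternatives to those reported. The minimum of 2000 UMIs and scaling by total counts were chosen after seeing the data. The cause of a change was not tested. Mitochondrial filters could not be run without such genes, and camera, fry, limma between classes and exact tests were not run, since each group counted as 1 sample. Of the alternative values of named genes 3694 stayed within the counting interval, 624 left it and 18 turned; of those of lists 3454 kept their side of the limits, 207 lost and 178 gained it, and 5 turned. A gene's ratio is said to turn only if it changed sign and its reported interval excluded 0, and a list only if its median lay beyond 1 limit of the random range as reported and beyond the opposite limit in the alternative. Changes of sign of other values, such as the median of efferocytosis genes, are not counted. No difference of *Clcf1* was detectable among the reported values of phagocytes, which held few UMIs of it.

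Thinning also left out cells under 1000 UMIs, such as 129 NC and 238 CO astrocyte-like and 18 and 136 choroid plexus-like cells, and these 2 steps were not told apart. So treated, genes at least 2-fold higher and lower in CO numbered 142 and 168 in T- or NK-like, 312 and 339 in astrocyte-like, 654 and 415 in choroid plexus-like, 95 and 112 in ependymal-like, 301 and 171 in neuroblast-like and 87 and 48 in oligodendrocyte-like cells; 209 were higher in monocyte- or dendritic-like and 301 lower in pericyte-like cells. At resolution 0.5 monocyte- or dendritic-like cells had 745 and 674, and with doublets oligodendrocyte-like cells had 34 lower.

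Shares, CO over NC, of microglia-like cells were 1.29 at resolution 0.5, 1.26 by marker score, 1.24 from 2000 UMIs and 1.23 without erythroid-like, neutrophil-like and unnamed cells. Oligodendrocyte-like cells were at 0.455 with doublets, 0.452 by score, 0.443 from 2000 UMIs and 0.446 with that denominator, and endothelial-like cells at 0.750 with it. By score, B-like (1.77), choroid plexus-like (0.794), ependymal-like (0.918), erythroid-like (0.648) and neuron-like shares (1.81) turned, and monocyte- or dendritic-like were 0.926, neutrophil-like 1.998, pericyte-like 1.01, proliferating 1.64 and smooth muscle-like 0.459. From 2000 UMIs choroid plexus-like turned to 0.964, astrocyte-like were 1.12 and neutrophil-like 11.4. Neutrophil-like with doublets were 1.88, and monocyte- or dendritic-like at resolution 0.5 0.313. Without 1 library choroid plexus-like shares ranged from 1.79 to 2.25.

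The NF-κB component median in macrophage-like cells was -0.088 thinned, -0.24 by score, -0.22 from 2000 UMIs and -0.42 to -0.18 without 1 library. The CLCF1 list in microglia-like cells was 0.23 with doublets, 0.18 by score and 0.17 to 0.22 without 1 library; in both phagocyte classes it was 0.12 to 0.20 without 1 library. List medians that turned were NF-κB targets in astrocyte-like (-0.44), cytokines in monocyte- or dendritic-like (0.37) and hemoglobin in oligodendrocyte-like cells (-0.44) by score, cytokines in endothelial-like cells thinned (0.38) and homeostatic microglia in neuroblast-like cells with doublets (1.27).

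Log2 ratios that turned by score were *Pomc* in astrocyte-like (0.0093), *Bcl2a1* (0.024), *Hba-a1* (0.052), *Hbb* (0.20) and *Alas2* (0.18) in endothelial-like and *Mertk* (0.027) and *Plat* (0.63) in macrophage-like cells. With doublets, *Il1b* (0.036), *Itgb3* (0.53), *Rac2* (0.48) and *Selplg* (0.25) in endothelial-like and *Kcnk13* in neuroblast-like cells (2.09) turned. In macrophage-like cells *Birc3* (0.35) and *Lef1* (0.0095) turned at resolution 0.5, *Rela* thinned (0.051) and *Mertk* without CO replicate 03 (0.025; range -0.42 to 0.025). *Il1b* in both phagocyte classes turned by total counts (-0.015) and thinned (-0.090).

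With libraries as replicates and the replicate number as a block, edgeR called 4270 genes in microglia-like, 742 in macrophage-like and 4305 in both classes. Correlations between same-numbered libraries were -0.040 to 0.025. Averaged over genes, libraries of a group differed about as random splits do, so this cannot tell whether the numbers mark pairs. A 2-fold minimum left 548, 431 and 549, thinning 2111, 289 and 2172, against 4395, 864 and 4427. Macrophage-like calls were 507 at resolution 0.5 and 473 to 689 without 1 library.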

Other observations

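Heat shock genes, which encode chaperones, had a negative median log2 ratio in each of the 11 classes, from -0.68 in choroid plexus-like to -0.055 in T- or NK-like cells, where it was above 0 with doublets kept, thinned cells, naming by score or without CO replicate 03. In T- or NK-like (percentile 25.1) and ependymal-like cells (percentile 6.30) it lay within the random range, as it did without NC replicate 02 in monocyte- or dendritic-like (-0.12) and without NC replicate 03 in neuroblast-like cells (-0.15) and with thinned cells in choroid plexus-like cells (-0.075). Interferon response genes were lower in 16 of 20 cases in ependymal-like (median -1.17, below all 10000 random lists), 18 of 20 in choroid plexus-like (median -0.68, below all 10000 random lists) and 20 of 24 in monocyte- or dendritic-like cells (median -0.52, percentile 0.03; 215 NC and 58 CO cells in 1 cluster, 86 and 66 in the other), and stood at 0.10 in microglia-like cells (percentile 95.3). All 16 measured glycolysis enzymes were higher in CO astrocyte-like cells (median 0.45, above all 10000 random lists), as were all 12 measured nuclear subunits of cytochrome c oxidase, the respiratory enzyme that CO can bind (median 0.39, percentile 99.97). Of these cells 144 NC and 348 CO cells lay in a cluster with a median of 769 UMIs and the glycolysis gene *Aldoc* among its leading genes, and 233 and 217 in another that was the largest in NC. Both medians also lay above the random range from 2000 UMIs. In neuroblast-like cells immediate early genes were lower in 20 of 23 cases (median -0.34, below all 10000 random lists). Blood-brain barrier genes were higher in 15 of 15 cases in ependymal-like (median 2.22, above all 10000 random lists) and 17 of 18 in monocyte- or dendritic-like cells (median 1.63, above all 10000 random lists), classes that are not vascular.

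*Cga* and *Pomc*, which encode hormone precursors or subunits of the pituitary, were among the lowest ratios, and no list of such genes was tested. *Cga* was 6.98-fold lower in CO over all kept cells (log2 ratio -2.80, -3.43 without CO replicate 02 and -3.83 thinned), and *Pomc* was at 103 and 5.18 CPM in neuroblast-like cells (-4.31, -4.97 without CO replicate 03 and -5.30 thinned). In astrocyte-like cells *Pomc* was at -6.16, and at 0.0093 by marker score. The labels give the tissue of both groups as cerebral hemisphere, and no explanation was tested.

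The test of myelin genes was chosen after the values were seen, while that of neighbouring genes and the count of other splits of the libraries were set down beforehand. How the outcomes for myelin and for neighbouring genes were read was changed once their values were known.

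Myelin genes were lower in CO microglia-like cells, and free RNA from oligodendrocytes is a candidate explanation. Over 19 genes the log2 ratio in microglia-like cells minus that in barcodes under the cell filter had a median of -0.049, near the 0 that free RNA needs, and 12 genes lay within 0.5 of 0. The others lay on both sides, among them *Cldn11* at -0.99 and *Tf* at 1.02. The lowest, *Myrf* at -3.70, rested on a low level in these barcodes (8.19 CPM in NC and 23.2 CPM in CO). Besides, 4 genes, *Mbp* (0.15), *Cnp* (0.10), *Aspa* (0.93) and *Tf* (0.47), were not lower in microglia-like cells at all. Free RNA and a difference within the cells therefore cannot be told apart for these genes, since members on both sides leave the median open. Uptake of myelin by microglia, and poisoning itself, stay open, untested.

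A genotype differing between the pools, meaning here the summed libraries of each group, might give neighbouring genes that stand apart together. Among 66 genes at least 2-fold apart in microglia-like cells, 2 pairs lay within 3 places in the gene order of the GRCr8 assembly. *Klf12* and *Tbc1d4* were both lower in CO (-1.77 and -1.19), while *Pdk4* and *Slc25a13* went in opposite directions (-1.03 and 1.30). The random median was 1 pair and the upper limit 3 pairs over 10000 sets matched on expression. The bound set beforehand took any count up to that limit as excluding genotype, which was wrong, since with such a median and limit a pair or so added by genotype would not pass it. Genotype and exposure therefore cannot be told apart for these genes.

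With the libraries treated as replicates, as first planned, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 4395 of 10886 genes in microglia-like (2172 higher), 864 of 7144 in macrophage-like (399 higher) and 4427 of 11086 in both classes together. DESeq2 called 3580, 602 and 3649. Macrophage-like calls were 473 without NC replicate 01, 473 without NC replicate 02 and 533 without NC replicate 03. In each class 1 of the 10 splits of the libraries, the real one, gave as many calls, and the highest of the others was 0; so few splits cannot give a share under 0.05. Since the libraries of a group differed, averaged over genes, about as much as random splits of its cells, these counts give no measure of differences between animals.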
